A study of Mus musculus with 7 samples.

How the data were processed

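The deposited values are counts of UMIs per gene and barcode, made by the submitters before deposit. Per the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 2.0.1. No read was realigned here. The deposited matrices hold all barcodes as well as a filtered set, and the filtered set was the source of cells here. The labels describe cells sorted by fluorescence from digested epithelium of adult mice in 7 groups of 1 library each. The Msi1 libraries were sorted for GFP, and the sorted fluorescence of the Lgr5 library differed. Libraries came from mice that carried the Msi1 or the Lgr5 recombinase allele, so the traced populations differ by construction.

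Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left out 165 of 18660 barcodes. Scrublet scores, computed within each library, called 34 further barcodes doublets, 0.182% of the total, far under the usual loading rate. Doublet removal therefore did not work well, and mixed cells may remain within the classes. Counts were summed over the cells of a library or class and divided by their total UMIs to give CPM, which was computed here. Exact Poisson intervals were used for levels, exact conditional intervals for ratios and exact binomial intervals for shares, at the 95% level. All of them cover counting error in 1 library only. No replicate check exists for any group, and no p-value or count of changed genes was made from cells.

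Cells of all libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1, without correction for library. Clusters were named from markers at least 2-fold above the other cells clustered with them. The type with the largest share of its markers raised gave the name, if at least 3 were. A cluster lost its name when another type had more markers among its top 10 genes, or when its cells were shallow and its own markers were absent there. Unnamed clusters with under 3 markers of every differentiated type form the remaining cells, together with the stem and cycling clusters. This set was chosen after the data had been seen. Folds within a class needed at least 50 cells in both libraries.

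Gene lists, 38 in all, were fixed before the data were examined, 14 for cell types and 24 for programs. Of the symbols in them 6 are absent from the files. The 12 genes always reported, the rule for naming others, the filters and most alternatives were also fixed before the data were examined. A list needed at least 3 members at 10 CPM in either library, and the lists for immune, stromal, endothelial, neural and red blood cells never reached this. The median log2 ratio of a list was placed among 10000 random lists, drawn from the 101 genes nearest to each member in expression, and a list was called higher or lower outside the 2.5 to 97.5 percentiles. This placement ranks the list against other genes of the same libraries and is no test across animals. Its interval came from 1000 Poisson draws. Members were counted as higher or lower at 2-fold with an interval that excludes 1, which is a rule of size.

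Beside the 12 fixed genes, the genes named were those with the 6 largest and 6 smallest log2 ratios per irradiated day, and the 10 largest and 10 smallest in the other comparisons, at 50 CPM or more in either library and with 1 CPM added. Mitochondrial genes, ribosomal protein genes and predicted models were left out. For each list described, up to 4 members with the largest absolute log2 ratio could be named, and genes that several parts of the rule name are given once. Some genes that the rule selects are not reported here. Further genes were named for the check of sex and after the counts of day 5 genes had been seen, among them Scand1 and Tmem238.

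For shares of cells with a transcript, every cell was thinned to 3000 UMIs, and no kept cell was shallower. Empty droplets were taken as barcodes of 1 to 50 UMIs. The share of free RNA was estimated from Paneth genes in tuft-like and enteroendocrine-like cells. A Paneth-like cell counted as above empty droplets when its UMIs of 10 alpha-defensin genes outside the marker list passed the normal limit for the level of the empty droplets of its library. Transcript sequences of GENCODE release M21 served for GC content and shared sequence. The fold and list methods were tested on simulated data for all 6 comparisons within the remaining cells, with 6961 or 6995 genes and 200 of them changed. All genes changed by 3-fold or 6-fold were recovered, 0 unchanged genes were called, and the intervals covered the true ratio in 94.5% to 97.5% of cases. Both simulated libraries were Poisson draws from the sums of the reference library, the model that the intervals assume. The simulation therefore checks the calculation only and holds no variation between animals or libraries. The lists raised in the simulation lay at percentile 100 and the unchanged lists between 4.04 and 57.4.

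The sex of cells was read from Xist and 4 Y-linked genes, with limits of at least 10 Xist UMIs or at most 4 that were set after their distribution had been seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, in a single thread with seed 1. Splicing, reads and barcodes outside the filtered set were not analysed here, apart from empty droplets and a count of barcodes.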

Results

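Gene expression was measured in single cells of the intestinal epithelium of adult mice by droplet-based sequencing of transcript 3' ends with unique molecular identifiers (UMIs), which tag single RNA molecules. The labelled cells carried a recombinase that tamoxifen activates, and fluorescent cells were isolated by flow sorting. The sorted fluorescence was GFP for the Msi1 libraries and differed for the Lgr5 library. In 6 libraries the recombinase was driven by Msi1, which encodes an RNA-binding protein, and the reporter was mTmG. In the other library it was driven by Lgr5, the receptor that marks crypt base columnar stem cells, from an allele that also encodes EGFP. There were 7 groups with 1 library each. The unirradiated Msi1 library taken after 15 h of tamoxifen served as day 0, and the libraries of days 1, 2, 3 and 5 followed 12 Gy of irradiation. A pair of unirradiated libraries, Msi1 and Lgr5, was taken after 2 days of tamoxifen.

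The filtered matrices held 18660 barcodes, of which 18461 cells were kept with 453949151 UMIs in all. Day 0 had 2465 cells and 70968602 UMIs, day 1 had 1305 cells and 48633345 UMIs, day 2 had 1354 cells and 51287338 UMIs, and day 3 had 3257 cells and 100120443 UMIs. Day 5 had 1733 cells and 31805281 UMIs. The Msi1 library of 2 days had 3632 cells and 70711974 UMIs, and the Lgr5 library had 4715 cells and 80422168 UMIs. The median depth ran from 15357 UMIs per cell in the Lgr5 library to 29697 at day 2. Because no group had a replicate, no difference was tested, and every interval covers counting error only, not the spread between animals.

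Xist, the RNA of the inactive X chromosome, and Y-linked genes showed the sex of the mice. The Msi1 library of 2 days was male, with Y-linked UMIs alone in 69.7% of cells. Day 0 held cells of both sexes, with at least 10 Xist UMIs and no Y-linked UMI in 1301 cells and the male pattern in 726. The irradiated and Lgr5 libraries were female. The cells of the male pattern at day 0 stood 2.55-fold (2.53 to 2.56) higher in Reg3b, a secreted antibacterial lectin, and 12.5-fold (11.1 to 14.1) higher in Lcn2, which binds bacterial siderophores, than the cells of the female pattern. Their MHC class II genes lay 1.15 higher in median log2 ratio, while the 6 measured interferon genes differed by 0.06. These differences arose within 1 library, but the sets also differ in sex and in median depth, at 27534 UMIs (male) and 21997 (female). They show that cells of 1 library can differ, and do not measure the spread between mice of 1 group.

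The cells formed 28 clusters, and 5 differentiated classes could be named from markers: Paneth-like, goblet-like, enterocyte-like, enteroendocrine-like and tuft-like. Paneth-like cells, which make antimicrobial peptides at the crypt base, were 10.6% (exact binomial interval 9.4 to 11.9) of cells at day 0, 32.3% (29.7 to 34.9) at day 1, 39.4% (36.8 to 42.1) at day 2, 13.8% (12.7 to 15.1) at day 3 and 0.404% (0.163 to 0.83) at day 5. Goblet-like, mucus-making cells were 1.42% (0.991 to 1.97) at day 0, 8.97%, 7.46% and 8.9% at days 1 to 3, and 30.6% (28.5 to 32.9) at day 5. Enterocyte-like, absorptive cells were 7.63% (6.61 to 8.75) at day 0, 4.83% at day 1, 0.96% (0.512 to 1.64) at day 2, and 0 of 3257 and 0 of 1733 cells at days 3 and 5, which allows up to 0.113% and 0.213%. Tuft-like cells, the chemosensory type, were 2.64%, 2.22%, 2.07%, 0.307% and 0.519% from day 0 to day 5, and hormone-making enteroendocrine-like cells 2.96%, 3.45%, 1.4%, 2.86% and 4.33%. With a minimum of 12049 UMIs per cell in every library the enteroendocrine-like share was 1.84% at day 3 and 1.08% at day 5. The higher share at day 5 was therefore not kept, and the tuft-like share on these days was 0.0322% and 0.166%. A further cluster of 43 day 5 cells with Paneth genes, at a median of 51305 UMIs, carried no name, and these cells were 2.48% of that library. It held 9 raised Paneth markers, but a myeloid marker and no Paneth marker stood among its top 10 genes. At resolutions 0.5 and 2 the Paneth-like share of day 5 was 2.89%, so the low share rests on this naming rule.

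Different clusters held the Paneth-like, goblet-like and enterocyte-like cells in different libraries, so part of each of these classes is library-specific. Enteroendocrine-like cells of all libraries lay in cluster 4 and tuft-like cells in cluster 7. Paneth-like cells lay in cluster 3 at day 0, in clusters 12 and 10 at days 1 and 2, in cluster 17 at day 3 and in cluster 23 in the Msi1 library of 2 days. Goblet-like cells lay in cluster 14 at days 1 to 3, in cluster 21, led by Retnlb, at day 5, and in clusters 6 and 16 in the libraries of 2 days. Enterocyte-like cells lay mainly in clusters 0 and 5 at day 0 and day 1, in clusters 9 and 5 in the Msi1 library of 2 days and in cluster 25 in the Lgr5 library. The stem and cycling crypt cells split almost wholly by library, so their numbers were not compared and they are treated together as the remaining cells. These were 74.8%, 48.3%, 48.7%, 74.1% and 61.6% of cells from day 0 to day 5. The lowest UMI total among the deposited cells was 8583 at day 0, 12049 at day 1, 10756 at day 2, 8688 at day 3 and 4789 at day 5, which can set the shares of small cells. With the minimum of 12049 UMIs in every library the day 1 Paneth-like share was 2.88 times that of day 0. The goblet-like and enterocyte-like shares depend on how cells were grouped. With each library clustered alone, goblet-like cells were 8.76% at day 0, 11.8% at day 1 and 20.4% at day 5. Enterocyte-like cells were then 9.2%, 6.13%, 6.02% and 12.8% at days 1, 2, 3 and 5, and Paneth-like cells 12.6% at day 5. Markers were in that case compared only among cells of the same library, so a class can be named at a low level. These shares therefore do not decide whether a class became scarce. At resolution 2 of the joint clustering, enterocyte-like cells were 0.246% at day 3 and 13.2% at day 5.

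**Figure D1:**
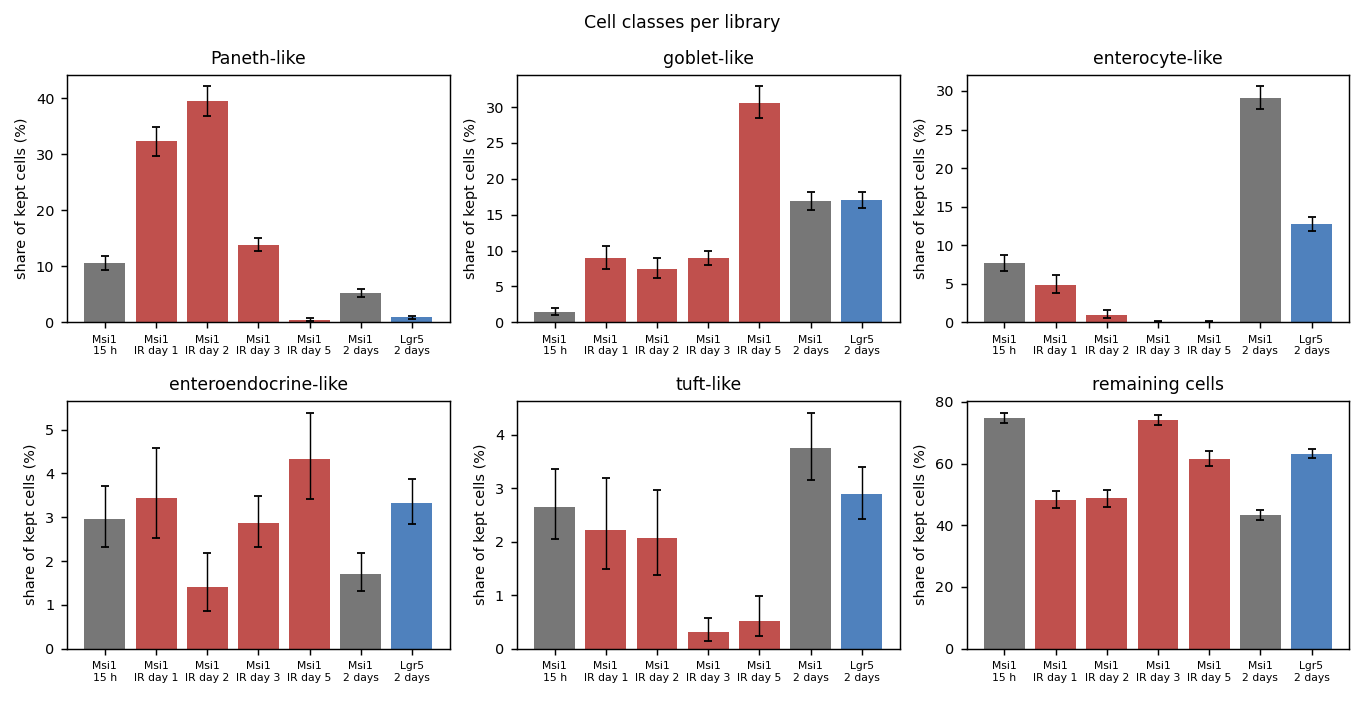
Share of kept cells in each class (percent, vertical axis) in the 7 libraries (horizontal axis), with exact binomial 95% intervals. Paneth-like cells reach 39.4% at day 2 and goblet-like cells 30.6% at day 5.

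The series design describes the Msi1-marked cells as resistant to DNA damage, and each irradiated library was set against day 0. With Paneth-like cells holding 58% and 59.6% of the UMIs at days 1 and 2, the median log2 ratio of all genes in the whole library lay at -0.92 at day 1 and -0.72 at day 2. At day 3 it was 0.09 and at day 5 -0.18. Within the remaining cells it was -0.05, 0.15, 0.16 and -0.16. Values within the remaining cells, a set chosen after the data were seen, are therefore given for several lists and a few genes. A list is called higher or lower only against random lists of matched expression. Most folds of single genes are of the whole library only. The remaining cells held 67.7% of the UMIs at day 0, and 31.8% and 33.8% at days 1 and 2. Whole-library folds of their genes on those days therefore mix the share of these cells with any change within them. A list median named below lay outside the central 95% of those lists unless stated. Measured members are those at 10 CPM or more in either library of a pair, so they differ between days. A member low at day 0 enters only where the later day is high, and the reverse, so counts of 2-fold members are favoured. Genes of the random lists pass the same limit. All 4 days share the same day 0 library, so any peculiarity of that library enters all of them.

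At day 1, p53 target genes stood higher and genes of the cell cycle, of crypt base stem cells, of antigen presentation and of antibacterial defence stood lower. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 7.61-fold (7.31 to 7.93) higher at 295 against 38.7 CPM (UMIs of a gene scaled to a common library total). Reg3b was 41.8-fold (41 to 42.5) lower, and Olfm4, a stem cell marker, was 17.2-fold (13.9 to 21.7) lower. The alpha-defensins of Paneth cells were higher in the whole library, where Paneth-like cells had a larger share.

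Of 17 measured p53 targets, 12 were at least 2-fold higher and 0 lower at day 1, with a median log2 ratio of 2.02 (1.91 to 2.17), and within the remaining cells all 20 measured were higher, with a median of 2.94 (2.76 to 3.10). Phlda3, which restrains Akt signalling, was 38.4-fold (32.4 to 45.9) higher, the kinase gene Plk2 14-fold (11.2 to 17.6), the stress cytokine Gdf15 9.77-fold (8.11 to 11.9) and Zmat3 7.68-fold (6.63 to 8.93). Mdm2, the ubiquitin ligase that degrades p53, was 2.62-fold (2.41 to 2.86) higher in the whole library and 5.1-fold (4.59 to 5.66) higher in the remaining cells. Crip2, a LIM domain protein gene, was 77.5-fold (57.9 to 106) higher. Of 6 measured members of the regenerative or fetal-like list, 5 were higher, with a median of 2.49 (2.35 to 2.65), led by the EGF receptor ligand Areg at 52.5-fold (38 to 74.5), the chaperone gene Clu at 19.5-fold (15.3 to 25.1) and the annexin gene Anxa3 at 10.3-fold (8.33 to 12.9). Ly6a, which encodes the surface protein Sca-1, was 2.02-fold (1.66 to 2.46) higher, and Anxa1 5.72-fold (3.07 to 11.5) higher at only 1.05 CPM. Immediate early genes were higher, at 0.68 (0.61 to 0.75), with 4 of 12 members past 2-fold, among them Atf3 at 9.13-fold (7.69 to 10.9), Dusp1 at 3.5-fold (3.14 to 3.92) and Junb at 2.26-fold (2.15 to 2.38).

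S phase genes lay at -1.40 (-1.44 to -1.33) in the whole library at day 1, with 33 of 38 members lower, and G2 and M phase genes at -1.50 (-1.55 to -1.43), with 38 of 47 lower and 2 higher. Within the remaining cells the medians were -0.34 and -0.42. The proliferation marker Mki67 was 4.11-fold (3.84 to 4.4) lower in the whole library and 1.9-fold (1.76 to 2.05) lower in the remaining cells, and Top2a, a topoisomerase, was 4.12-fold (3.94 to 4.31) lower. Homologous recombination and Fanconi genes lay at -1.52 (-1.61 to -1.33), with 4 of 5 lower, but inside random lists against the Msi1 library of 2 days. The crypt base columnar stem list lay at -1.55 (-1.61 to -1.48), with 9 of 11 members lower, and at -0.49 in the remaining cells. In those cells it lay at -0.35, inside random lists, against the Msi1 library of 2 days. Lgr5 was 3.6-fold (3.28 to 3.96) lower, Gkn3 9.52-fold (8.19 to 11.1), Smoc2 3.59-fold (3.4 to 3.8) and the transcription factor gene Ascl2 2.66-fold (2.51 to 2.82). Msi1 itself stood at 2.28 against 7.06 CPM. Antimicrobial genes lay at -1.93 (-2.06 to -1.80), with 6 of 8 members lower and 1 higher. Lcn2 was 114-fold (74.7 to 185) lower, Reg3g 5.99-fold (5.93 to 6.06) and Reg1 3.89-fold (3.73 to 4.05). Day 1 was female, while at day 0 Lcn2 stood at 111 CPM in male-pattern and 8.87 CPM in female-pattern cells. Reg3g stood there at 7871 against 2791 CPM and H2-Aa at 28.1 against 9.99 CPM. On every day the folds of these genes therefore depend on the mix of sexes at day 0. All 5 measured MHC class II genes were lower, with a median of -2.80 (-2.93 to -2.66), H2-Aa by 15.1-fold (11.6 to 20), H2-Ab1 by 6.99-fold (6.3 to 7.77) and the invariant chain gene Cd74 by 4.46-fold (4.28 to 4.66). Interferon response genes lay at -1.23 (-1.34 to -1.11), inside the range of random lists, but at -3.17, below it, against the Msi1 library of 2 days. The other lowest genes were the carbonic anhydrase Car4 at 22.1-fold (18.9 to 26), the histone gene Hist1h2ap at 13.4-fold (12.8 to 14.1), the mucosal scavenger protein gene Dmbt1 at 12.5-fold (12.1 to 13.1) and the sialyltransferase St3gal4 at 8.01-fold (7.26 to 8.85).

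The Paneth list lay at 2.00 (2.00 to 2.01) in the whole library at day 1, all 9 members higher, and at -0.29 in the remaining cells. Defa20 was 23.9-fold (23.7 to 24.1) higher, Defa22 13.8-fold (13.7 to 13.9), Defa21 13.6-fold (13.5 to 13.7) and Defa17 8.5-fold (8.43 to 8.57), but near-identical defensin genes can share reads, so single members are uncertain. Lyz1, the Paneth lysozyme, was 4-fold (3.99 to 4.02) higher. The goblet list lay at 1.37 (1.36 to 1.38), with 7 of 10 members higher, among them Guca2a at 4.7-fold (4.63 to 4.77) and the lectin gene Zg16 at 3.84-fold (3.79 to 3.9). The enterocyte list lay at -0.36, above its random lists, and with the Msi1 library of 2 days as the reference it lay at -2.09, below them. With that reference the stem list lay at -0.49, above its random lists, S phase genes at -0.84 and goblet genes at -0.66, inside theirs, and Ly6a was lower at day 1, at a ratio of 0.165. Msi1, Ascl2 and Reg3g turned too, to ratios of 1.83, 1.02 and 1.27, as did Lcn2 in the remaining cells, to 13.9, and the Paneth list there, to 1.12. These directions therefore rest on the choice of unirradiated library.

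At day 2 the p53 targets stood further from day 0 and the regenerative genes stood far above it, while cycling and stem cell genes stayed below day 0. Areg was 173-fold (126 to 245) higher, Ly6a 67.7-fold (58.4 to 79), Clu 76.7-fold (60.8 to 98) and Anxa3 77.6-fold (63.5 to 95.8). Of 10 measured regenerative or fetal-like genes, 8 were higher and 0 lower, with a median log2 ratio of 6.27 (6.10 to 6.50), and within the remaining cells all 10 were higher, at 7.48 (7.32 to 7.71). Only 3 members of this list reached 10 CPM among the male or female cells of day 0. Members low at day 0 therefore entered through their level at day 2, and their being higher follows from that limit. Car4 was 171-fold (113 to 274) lower and Lgr5 5.13-fold (4.61 to 5.71) lower.

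The interleukin 1 receptor antagonist gene Il1rn was 155-fold (91.9 to 284) higher at day 2, the alarmin Il33 123-fold (68.5 to 248), and Anxa1 270-fold (158 to 508). Of 19 measured p53 targets, 16 were higher and 0 lower, with a median of 2.51 (2.39 to 2.69), and all 22 were higher within the remaining cells, at 3.59 (3.46 to 3.76). Cdkn1a was 8.93-fold (8.58 to 9.3) higher, Mdm2 6.92-fold (6.42 to 7.46), Phlda3 57.8-fold (48.8 to 69), Plk2 28.3-fold (22.8 to 35.5), Gdf15 15.8-fold (13.1 to 19) and Crip2 208-fold (156 to 284). S phase genes lay at -1.46 (-1.52 to -1.42), with 30 of 38 lower, and G2 and M phase genes at -1.38 (-1.49 to -1.33), with 36 of 47 lower and 2 higher, against -0.46 and -0.33 in the remaining cells. Against the Msi1 library of 2 days the S phase list lay at -1.001, inside random lists. Mki67 was 5.31-fold (4.93 to 5.73) lower. The stem list lay at -1.64 (-1.74 to -1.59), with 10 of 11 members lower and 1 higher. Over all kept cells it lay at -0.76, inside random lists, against the Msi1 library of 2 days. In the remaining cells 6 of 11 were lower and 1 higher. There the list kept its call under every alternative, from -1.11 to -0.48. Olfm4 was 19.1-fold (15.3 to 24.2) lower, Ascl2 4.19-fold (3.91 to 4.49) and Msi1 3.12-fold (2.55 to 3.85), but against the Msi1 library of 2 days Msi1 stood at a ratio of 1.82.

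Interferon genes lay at 0.37 (0.28 to 0.48) at day 2, with 3 of 9 members higher, and at 1.12 in the remaining cells. Zbp1, a sensor of nucleic acids, was 3.79-fold (3.22 to 4.47) higher, the transcription factor gene Irf7 3.53-fold (3.13 to 3.98) and Isg15, a ubiquitin-like modifier, 2.55-fold (2.25 to 2.89). With the Msi1 library of 2 days as reference the same list lay at -2.06. MHC class II genes, at -0.14 (-0.21 to -0.07), lay inside the range of random lists, but above it, at 0.54, against the female cells of day 0 and below it, at -1.67, against the Msi1 library of 2 days. Antimicrobial genes lay at -2.30 (-2.31 to -2.27), with 6 of 8 lower and 1 higher, and at -0.36, above random lists, against the Msi1 library of 2 days. Reg3b was 7.28-fold (7.23 to 7.34) lower, Reg3g 2.02-fold (2 to 2.03) and Lcn2 11-fold (9.6 to 12.6), while against the Msi1 library of 2 days Reg3b and Reg3g were higher, at ratios of 1.85 and 3.78. All 9 Paneth genes were higher, at 2.14 (2.12 to 2.16), with Defa17 at 12.9-fold (12.8 to 13), but their median in the remaining cells was -0.56, and 1.08 against the Msi1 library of 2 days. The goblet list lay at 1.17 (1.15 to 1.23), or at -0.39, still above random lists, against the Msi1 library of 2 days, with Spink4 4.42-fold (4.4 to 4.44) and the secretory transcription factor gene Atoh1 2.99-fold (2.74 to 3.25) higher, and at -2.21 in the remaining cells. In those cells it lay at -0.26, inside random lists, against the Msi1 library of 2 days. The enterocyte list lay at -1.17 (-1.19 to -1.14), with 7 of 12 lower, including sucrase-isomaltase, Sis, at 3.79-fold (3.5 to 4.11), and Apoc3 at 3.51-fold (3.15 to 3.9), but with every cell weighted equally it lay at -0.52, inside random lists. The other lowest genes were Dmbt1 at 25.4-fold (24.1 to 26.9), Hist1h2ap at 22.3-fold (21.1 to 23.7), the arginase gene Arg2 at 24.1-fold (20.9 to 27.8), the vitamin D receptor gene Vdr at 17.6-fold (15.7 to 19.7) and the zinc transporter gene Slc39a5 at 16.7-fold (14.7 to 19.1).

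At day 3 the regenerative genes lay at 6.98 (6.61 to 7.28), their highest median of the 4 days over all kept cells. In the remaining cells they lay at 7.07, where day 2 stood higher. The members measured differ between days, so these medians are of partly different genes. Genes of the interferon response, MHC class II and antioxidant defence were higher, while genes of absorptive cells were lower. Ly6a reached 936 CPM, 375-fold (324 to 437) above day 0, and Clu 188 CPM, 183-fold (146 to 234) above it. S phase and G2 and M phase genes lay at 0.02 and 0.21, inside the range of random lists, but S phase genes lay above it, at 0.62, against the Msi1 library of 2 days and below it, at -0.18, against the male cells of day 0, and G2 and M phase genes above it, at 0.34, with every cell weighted equally. The p53 targets were still higher, at 1.85 (1.76 to 1.98), with 13 of 16 members past 2-fold.

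Anxa1 was 576-fold (337 to 1082) higher at day 3, Areg 193-fold (140 to 273), the tryptophan-degrading enzyme gene Ido1 2170-fold (601 to 17926) and Ly6d 1993-fold (682 to 9666). The intervals of Ido1 and Ly6d are wide because day 0 held few UMIs of them, 0.0282 and 0.0423 CPM. Cdkn1a was 7.17-fold (6.89 to 7.45) higher, Mdm2 3.74-fold (3.48 to 4.04) and Phlda3 48.6-fold (41 to 57.9). Of 11 measured interferon genes, 9 were higher and 0 lower, at 1.91 (1.76 to 2.05), with the guanylate-binding protein gene Gbp2 at 20-fold (15 to 27.2), Zbp1 at 11.4-fold (9.86 to 13.2) and Iigp1 at 8.79-fold (7.2 to 10.8). Against the Msi1 library of 2 days the interferon list lay at -0.62, below random lists. MHC class II genes lay at 2.33 (2.29 to 2.37), with 5 of 6 higher, H2-Eb1 by 5.6-fold (5.37 to 5.84), H2-Aa by 5.36-fold (5.06 to 5.69) and Cd74 by 4.74-fold (4.66 to 4.83). Antioxidant genes lay at 1.19 (1.16 to 1.22), with 8 of 13 higher and 1 lower, led by the cystine transporter gene Slc7a11 at 13.4-fold (10.3 to 17.9), the glutathione transferase gene Gsta1 at 12.2-fold (11.5 to 13) and the glutathione peroxidase gene Gpx2 at 4.12-fold (4.09 to 4.15). Ribosome biogenesis genes lay at 0.73 (0.71 to 0.75), with 1 of 13 past 2-fold, Rrp9 at 2.21-fold (2.11 to 2.32).

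The stem list lay at -0.84 (-0.93 to -0.78) at day 3, with 5 of 11 members lower and 1 higher, and at -0.05, inside random lists, against the Msi1 library of 2 days. Lgr5 was 4.62-fold (4.28 to 4.99) lower, Olfm4 6.33-fold (5.72 to 7.01) and Msi1 4.5-fold (3.76 to 5.42), though Msi1 stood at a ratio of 1.26 against the Msi1 library of 2 days, while Ascl2 was 1.38-fold (1.33 to 1.43) and Mki67 1.44-fold (1.39 to 1.5) lower. Enterocyte genes lay at -2.54 (-2.61 to -2.47), with 10 of 12 lower, Apoc3 by 32.4-fold (26.2 to 40.5), Sis by 15.2-fold (13.6 to 17) and the fatty acid-binding protein gene Fabp1 by 13.1-fold (12.7 to 13.5), and lipid absorption genes at -1.84 (-1.90 to -1.77), with 8 of 13 lower. Tuft genes lay at -2.53 (-2.67 to -2.40), all 4 measured lower, with Rgs13 at 6.97-fold (6.2 to 7.85). Antimicrobial genes lay at -0.17 (-0.23 to -0.14), inside the range of random lists, but above it against the female cells of day 0, at 0.78, and the Msi1 library of 2 days, at 1.42, and below it against the male cells of day 0, at -0.84, with Reg3b 1.83-fold (1.83 to 1.84) lower and Reg3g 1.51-fold (1.51 to 1.52) higher. The other lowest genes were Arg2 at 109-fold (88.6 to 136), Car4 at 88.6-fold (71.4 to 111), the sulfotransferase gene Sult1d1 at 21.2-fold (19.3 to 23.2), the urea cycle gene Otc at 16.8-fold (15.7 to 18) and the prolactin receptor gene Prlr at 17-fold (15.5 to 18.7).

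At day 5 antimicrobial, goblet and interferon genes stood higher, regenerative genes remained far above day 0, and stem cell genes stood at their lowest. Reg3b held 51387 CPM against 9622 at day 0, 5.34-fold (5.33 to 5.36) higher, and Reg3g 33157 CPM, 6.93-fold (6.9 to 6.95) higher. Retnlb, a goblet cell defence protein, was 171-fold (155 to 189) higher. The stem list lay at -2.58 (-2.72 to -2.38), with 10 of 11 members lower and 1 higher.

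Antimicrobial genes lay at 2.30 (2.24 to 2.35) at day 5, with 7 of 10 higher and 1 lower. The oxidase maturation gene Duoxa2 was 34.2-fold (31.2 to 37.5) higher, Reg4 8.2-fold (8.07 to 8.34) and Lcn2 3.13-fold (2.99 to 3.26). The goblet list lay at 2.32 (2.31 to 2.34), with 8 of 10 higher and 1 lower, Agr2 by 14.8-fold (14.7 to 15), Spdef by 9.17-fold (8.48 to 9.93) and Atoh1 by 6.84-fold (6.31 to 7.43), and at -0.85 in the remaining cells. In those cells it lay inside random lists against the Msi1 library of 2 days, at 0.55, and with every cell weighted equally, at -0.48. Enteroendocrine genes lay at 1.79 (1.70 to 1.87), with 9 of 12 higher, led by the tachykinin gene Tac1 at 18-fold (16.7 to 19.5) and Tph1, which makes serotonin, at 13-fold (10.6 to 16). Interferon genes lay at 2.35 (2.24 to 2.43), with 9 of 12 higher, Ifit1 by 19.4-fold (15 to 25.7) and Usp18 by 17.6-fold (13.4 to 23.4), and at -0.75, inside random lists, against the Msi1 library of 2 days. MHC class II genes lay at -1.05 (-1.14 to -0.96), with 4 of 6 lower, and at -0.38, inside random lists, against only the female cells of day 0. They also lay inside random lists, at -1.04, with the stricter cell filter and with free RNA subtracted. Regenerative genes lay at 5.39 (5.11 to 5.75), with 7 of 9 higher, Ly6a by 276-fold (238 to 322), Anxa1 by 363-fold (212 to 684), Il33 by 272-fold (152 to 546), Anxa3 by 62.1-fold (50.7 to 76.8) and Clu by 42.1-fold (33.2 to 54). Ly6d and Ly6c1 were 1630-fold (557 to 7908) and 342-fold (195 to 663) higher. The p53 targets lay at 0.77 (0.66 to 0.83), with 2 of 10 higher and 1 lower. Cdkn1a was 4.5-fold (4.3 to 4.71) and Mdm2 1.65-fold (1.49 to 1.84) higher, while Phlda3 stood at 2.36 against 1.93 CPM.

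Unfolded protein response genes lay at 1.19 (1.04 to 1.33) at day 5, with 6 of 11 higher, led by Trib3 at 44.7-fold (32.9 to 62.2) and Chac1 at 32.5-fold (23.4 to 46.4), and glycolysis genes at 1.05 (0.96 to 1.15), with 6 of 11 higher, led by the glucose transporter gene Slc2a1 at 5.03-fold (4.49 to 5.63). Ascl2 was 19.6-fold (16.5 to 23.6) lower, Olfm4 11.4-fold (9.16 to 14.4), Lgr5 5.98-fold (5.19 to 6.92) and Msi1 12.5-fold (7.81 to 21.2). S phase and G2 and M phase genes, at -0.39 (-0.51 to -0.35) and -0.43 (-0.51 to -0.40), lay inside the range of random lists, but below it, at -0.66 and -0.61, against the male cells of day 0, with Mki67 2.57-fold (2.4 to 2.75) lower than in the whole of day 0. G2 and M phase genes also lay below it against the Msi1 library of 2 days, at -0.53, and with the stricter filter or free RNA subtracted, at -0.48. Both other scalings, at -0.17 and -0.37, gave the same call, as did S phase genes with every cell weighted equally, at -0.51. The lowest genes were Hist1h2ap at 1513-fold (845 to 3031), Scand1 at 213-fold (145 to 326), Tmem238 at 60.4-fold (50.5 to 72.7), the growth factor gene Nrtn at 130-fold (77.1 to 237), Chchd10, which encodes a mitochondrial protein, at 36.6-fold (33.7 to 39.8) and the hormone somatostatin, Sst, at 60-fold (43.1 to 86.2). In this library 88 genes stood at least 4-fold below every other library, Ascl2, Hist1h2ap, Scand1, Tmem238, Chchd10 and Sst among them, against 0 to 14 such genes in each other library.

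Within Paneth-like cells the p53 targets lay at 0.34, 0.39 and 1.34 at days 1, 2 and 3. Their regenerative list lay at 2.12 and 7.88 and their interferon list at -0.02 and 2.25 at days 2 and 3, while both lists lay inside random lists at day 1. Within enteroendocrine-like cells, all from cluster 4, the p53 targets lay at 1.76 at day 3 and 1.37 at day 5, the regenerative list at 6.31 and 3.68, and the unfolded protein response at 0.82 and 1.59. Within enterocyte-like cells, of which day 1 held 63, the p53 targets lay at 1.94, G2 and M phase genes at -2.66 and antimicrobial genes at -2.88.

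Cell cycle transcripts were also counted per cell after thinning every cell to 3000 UMIs, which left out no cell. At least 10 UMIs of the G2 and M phase list, a limit chosen after the data were seen, were found in 53.2% (50.9 to 55.5) of the remaining cells at day 0, 52.7% (48.7 to 56.7) at day 1, 41.1% (37.3 to 45.0) at day 2, 75.3% (73.6 to 77.1) at day 3 and 57.3% (54.3 to 60.3) at day 5. For the S phase list these shares were 27.6%, 20.2%, 22.2%, 37.3% and 28.4%. The unirradiated Msi1 library of 2 days held 71.2% (68.9 to 73.5) for G2 and M phase and 36.3% for S phase, near the shares of day 3. Against that library the G2 and M phase list of the remaining cells at day 3 lay at -0.33, below random lists. The higher shares at day 3 therefore rest on the choice of unirradiated library. At the lower threshold of 3 UMIs, the one fixed at the outset, the G2 and M phase shares were 91.4%, 87.8%, 82.1%, 94.9% and 89.7% and the S phase shares 89.3%, 80.6%, 64.2%, 82.7% and 72.2%, so the G2 and M phase measure was near saturation. Free RNA in the droplets also contributes to such counts, and its share, estimated from Paneth genes, was 12.3% at day 0 and 5.19% to 8.33% in the irradiated libraries. Hemoglobin, at 6371 CPM in empty droplets and 0.288 CPM in kept cells of day 1, goes against a share of this size if it was spread over all droplets. That spread was not examined. The share of free RNA is therefore uncertain.

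The Msi1 and Lgr5 libraries of 2 days show how the cells traced by each recombinase differ in unirradiated epithelium. The Msi1 library held more Paneth and enterocyte transcripts and higher interferon genes, and the Lgr5 library held more transcripts of stem cells and enteroendocrine cells. Paneth-like cells were 5.2% (4.5 to 5.98) of the Msi1 library and 0.87% (0.625 to 1.18) of the Lgr5 library, and enterocyte-like cells 29.1% (27.6 to 30.6) and 12.7% (11.8 to 13.7). The enterocyte-like difference depends on the grouping, since resolution 0.5 turned it, to 26.5% and 34.9%, and with each library clustered alone the Msi1 share was 13.9%. Goblet-like cells were 16.9% and 17.0%, tuft-like cells 3.74% and 2.88%, and enteroendocrine-like cells 1.71% and 3.33%. With the minimum of 12049 UMIs in every library the tuft-like share of the Msi1 library fell to 1.6%, below that of the Lgr5 library. The enteroendocrine-like share of the Lgr5 library fell to 1.98%. Msi1 RNA itself was 11.2-fold (8.99 to 14.1) lower in the Msi1 library, at 1.24 against 13.9 CPM. These libraries differ in sex, with Xist 2845-fold (1955 to 4317) lower in the Msi1 library. They also differ in reporter and sorted fluorescence as well as in recombinase.

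All 9 Paneth genes were higher in the Msi1 library, with a median log2 ratio of 2.68 (2.67 to 2.69) and, in the remaining cells, 1.75. Empty droplets also differed, with 69801 CPM of Paneth genes in the Msi1 and 20630 CPM in the Lgr5 library, so the value of the remaining cells does not separate their own RNA from free RNA. Defa20 was 16.7-fold (16.5 to 16.9) higher, Defa22 15.7-fold (15.5 to 15.9), Defa21 14.7-fold (14.5 to 14.9), and Defa26, Defa17, Defa5, Defa3 and Defa23 between 7.96-fold and 10.8-fold. Clps, a cofactor of pancreatic lipase, was 7.69-fold (7.52 to 7.86) and the pentraxin gene Mptx1 7.17-fold (6.94 to 7.41) higher. Enterocyte genes lay at 0.97 (0.95 to 0.98), with 7 of 14 higher and 1 lower, led by the lactase gene Lct at 5.02-fold (4.53 to 5.57) and the apolipoprotein gene Apoa1 at 4.32-fold (4.25 to 4.39), and at 0.06, inside random lists, in the remaining cells. Lipid absorption genes lay at 1.18 (1.13 to 1.28), with 8 of 13 higher. Interferon genes lay at 1.18 (1.14 to 1.24), with 8 of 13 higher, and at 1.17 in the remaining cells, led by Ifit3 at 10.3-fold (8.42 to 12.8), Ifit1 at 6.74-fold (6.06 to 7.52) and Isg15 at 4.75-fold (4.54 to 4.97). Ly6a was 4.72-fold (4.29 to 5.2) higher. Tuft genes lay at 0.95 (0.87 to 1.02), with 3 of 7 higher.

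The stem list lay at -0.79 (-0.89 to -0.70) in the Msi1 against the Lgr5 library, with 5 of 11 members lower, and at -0.28 in the remaining cells. Gkn3 was 4.04-fold (3.83 to 4.27) lower, Igfbp4 2.74-fold (2.58 to 2.91) and Ascl2 2.62-fold (2.49 to 2.75), while Lgr5 was 1.47-fold (1.37 to 1.59) lower over all cells and 1.05-fold (0.966 to 1.14) lower in the remaining cells. Olfm4 went the other way, 1.89-fold (1.77 to 2.03) higher, as did Mki67, 1.35-fold (1.31 to 1.4). Prom1, another stem cell gene, was 3.29-fold (3.09 to 3.49) lower and the microtubule regulator Stmn1 3.33-fold (3.26 to 3.39). S phase and G2 and M phase genes lay at -0.40 and -0.28 over all cells but at 0.24 and 0.23, above random lists, in the remaining cells, and with every cell weighted equally the G2 and M phase list over all cells lay at -0.12, inside random lists. Enteroendocrine genes lay at -1.16 (-1.23 to -1.01), with 4 of 7 lower, including Tac1 at 4.76-fold (4.28 to 5.31), Chgb at 2.46-fold (2.37 to 2.55) and Neurog3, the regulator that specifies these cells, at 2.26-fold (2.03 to 2.53), and the appetite hormone gene Ghrl was 3.2-fold (3.05 to 3.36) lower. Immediate early genes lay at -0.68 (-0.70 to -0.64), with Dusp1 2.39-fold (2.12 to 2.69) lower. The other lowest genes were Adh6a at 5.86-fold (5.58 to 6.15), the metallothionein gene Mt2 at 5.69-fold (5.43 to 5.96), Rgcc at 4.52-fold (4.23 to 4.84) and the adhesion gene Amica1 at 3.07-fold (2.96 to 3.19).

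Msi1 tracing at 2 days against 15 h shows how the labelled population differed with time. At 2 days enterocyte, goblet, tuft and interferon genes were higher, and stem cell genes and the antibacterial lectins were lower. Enterocyte-like cells were 29.1% at 2 days and 7.63% at 15 h, goblet-like cells 16.9% and 1.42%, and Paneth-like cells 5.2% and 10.6%. With each library clustered alone the enterocyte-like share at 2 days was 13.9% and the goblet-like share at 15 h was 8.76%, so these differences were smaller. That naming, however, compared markers only among cells of the same library. Isg15 was 25.2-fold (22.8 to 28) higher and Reg3b 13.5-fold (13.3 to 13.6) lower. The 15 h library held both sexes and the 2 day library males only, with Xist 1916-fold (1317 to 2908) lower.

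Enterocyte genes lay at 1.96 (1.92 to 2.01), with 12 of 14 higher and 1 lower, Lct by 6.79-fold (6 to 7.7), the peptidase gene Anpep by 5.91-fold (5.67 to 6.16) and Fabp1 by 4.97-fold (4.92 to 5.02). Lipid absorption genes lay at 1.68 (1.63 to 1.75) and sugar, peptide and brush border genes at 1.39 (1.35 to 1.43). The goblet list lay at 1.72 (1.70 to 1.74), with 9 of 10 higher, Zg16 by 6.16-fold (6.08 to 6.24), Agr2 by 5.92-fold (5.85 to 5.98) and Clca1 by 5.31-fold (5.11 to 5.53), and at -1.61 in the remaining cells. All 7 measured tuft genes were higher, at 1.19 (1.13 to 1.28). Interferon genes lay at 2.85 (2.65 to 3.08), with 11 of 13 higher, and at 2.37 in the remaining cells, 2.53 in enterocyte-like, 3.29 in tuft-like, 2.09 in enteroendocrine-like and 0.70 in Paneth-like cells. Ifit1 was 37.1-fold (28.9 to 48.5) higher, Rtp4 15.9-fold (13.9 to 18.1), Irf7 13.7-fold (12.4 to 15.3), Ifi27l2a 11.2-fold (9.98 to 12.5), Ly6a 12.3-fold and H2-T23, a nonclassical MHC class I gene, 8.08-fold (7.32 to 8.94). MHC class II genes lay at 1.30 (1.27 to 1.34), with 4 of 6 higher, including H2-Aa at 3.17-fold (2.97 to 3.38). Gsta1 was 10.3-fold (9.67 to 11) higher, Defa20 6.5-fold (6.46 to 6.55) and Rnaset2b 6.44-fold (5.9 to 7.04).

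The stem list lay at -0.92 (-1.01 to -0.86) at 2 days against 15 h, with 5 of 11 members lower, and at -0.30 in the remaining cells. Lgr5 was 2.56-fold (2.39 to 2.75) lower, Ascl2 2.71-fold (2.58 to 2.85), Igfbp4 2.83-fold (2.67 to 3) and Msi1 5.67-fold (4.51 to 7.2), while Olfm4 stood at 30.3 and 29.8 CPM. Wnt targets lay at -0.92, with 5 of 11 lower. The S phase list lay at -0.43 (-0.48 to -0.40) over all cells and, inside random lists, at 0.21 in the remaining cells. The G2 and M phase list lay at 0.01 over all cells, inside random lists, and at 0.51 in the remaining cells. Mki67 was 1.4-fold (1.35 to 1.44) higher. Reg3g was 7.61-fold (7.54 to 7.69) lower, while the antimicrobial list lay at 0.30, inside random lists, over all cells and at -1.11 in the remaining cells. The other lowest genes were Mt2 at 14.8-fold (14.1 to 15.5), Mt1 at 4.74-fold (4.66 to 4.82), Hist1h2ap at 5.77-fold (5.62 to 5.93), the homeodomain gene Hopx at 4.49-fold (4.26 to 4.74), Tifa at 3.89-fold (3.62 to 4.18) and Nrtn at 3.8-fold (3.55 to 4.07).

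Msi1 and Lgr5 transcripts were counted per cell at 3000 UMIs. Msi1 was found in 2.31% (1.76 to 2.99) of cells at day 0, 0.536% at day 1, 0.96% at day 2, 0.368% at day 3 and 0.0577% at day 5, in 0.413% (0.231 to 0.68) of the Msi1 library of 2 days and in 5.01% (4.4 to 5.67) of the Lgr5 library. Lgr5 was found in 13.5% (12.2 to 14.9) at day 0, 4.75%, 2.44%, 2.82% and 1.73% at days 1, 2, 3 and 5, 5.18% in the Msi1 library of 2 days and 8% (7.24 to 8.81) in the Lgr5 library. In goblet-like cells, which should lack both, Msi1 was found in 0 of 35 cells at day 0, which allows up to 10%, in 0.855%, 0%, 0.69% and 0.188% at days 1, 2, 3 and 5, in 0.163% of cells of the Msi1 library of 2 days and in 1.62% of the Lgr5 library. Lgr5 was found in 2.86%, 0%, 2.97%, 0.69% and 0.942% of goblet-like cells from day 0 to day 5, 0.651% in the Msi1 library of 2 days and 1.5% in the Lgr5 library. The goblet-like cells had median depths of 15492, 15667, 20489, 25655, 16302, 12813 and 14942 UMIs before thinning, and all kept cells 22840, 25410, 29697, 28526, 16419, 15837 and 15357. The interval of the Msi1 share lay above that of goblet-like cells only in the Lgr5 library, and that of the Lgr5 share lay above it at day 1 and in the Msi1 and Lgr5 libraries of 2 days. Both transcripts were found in 12 cells at day 0, 0.487% (0.252 to 0.849), where independent detection would give 0.312%, and in 38 cells of the Lgr5 library, 0.806% (0.571 to 1.1), where it would give 0.4%. Within the stem-like cells of the Lgr5 library both were found in 2.13% (1.51 to 2.93), where independent detection would give 2.09%, so the excess was not found within that class. Without thinning, Msi1 was found in 16.5% and Lgr5 in 50.9% of cells at day 0.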

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

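Barcodes outside the filtered set and free RNA were the only data in which a signal appeared that no comparison of the report uses, and both were flagged for that reason. At least 2000 UMIs were held by 898 barcodes outside the filtered set at day 0, 841 at day 1, 586 at day 2, 1068 at day 3, 448 at day 5, 1084 in the Msi1 library of 2 days and 606 in the Lgr5 library. Their cell types were not analysed here. The lowest UMI total in the filtered set was 8583, 12049, 10756, 8688, 4789, 8080 and 4499 in the same order.

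Hemoglobin RNA was found in empty droplets at 6371 CPM at day 1, 44661 CPM in the Msi1 library of 2 days and 598 CPM in the Lgr5 library, against 0 at day 5. The kept cells of those libraries held 0.288, 7.25 and 0.0746 CPM. Hemoglobin was therefore almost confined to droplets without a cell, and no cluster of red blood cells was named. If it was spread over all droplets, these values go against the share of free RNA in cells that was estimated from Paneth genes.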

How the results depend on the processing

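Each result was recomputed under 1 changed choice at a time. The alternatives were chosen before the data were examined, except for the male and female parts of the 15 h library as reference, the own clustering of each library, the common UMI minimum, the removal of high doublet scores and the limit of 10 UMIs, which were chosen after seeing the data. Of all recomputed results, 202 lists gained a call, 94 lists lost one and 33 lists or genes reversed. A further 993 gene ratios, shares or levels moved past their counting interval, also where the gene was past 2-fold, and 4756 results stayed the same. For lists this means an unchanged call, and for genes and shares a value inside the counting interval. Over all kept cells the p53 targets kept their call under every alternative, from 1.70 to 2.76 at day 1, 2.11 to 3.22 at day 2, 1.70 to 2.24 at day 3 and 0.47 to 1.03 at day 5. The regenerative genes kept theirs, from 1.63 to 3.89, 4.94 to 6.99, 5.58 to 7.12 and 4.49 to 5.66 on the same days. No paired analysis was possible because each group had 1 library and no label pairs the animals. Depth limits the detection of low genes such as Msi1, and no spread between animals could be set beside any of these values. With all doublets kept, no class share moved past its interval. The cause was not tested for any change below, and libraries are listed in the order day 0, day 1, day 2, day 3, day 5, Msi1 at 2 days and Lgr5. Values of lists are median log2 ratios. A list with under 3 measured members, or a class with under 50 cells in a library, gave no value. The Paneth list of the remaining cells lay from 1.56 to 11.23 between the Msi1 and Lgr5 libraries of 2 days and from -11.84 to -1.13 at day 5, with the far ends when free RNA was subtracted, so its size there depends on how free RNA is treated.

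With the Msi1 library of 2 days as reference, over all kept cells, lists on the opposite side of random lists were stem -0.49, enterocyte -2.09, tuft -1.47, lipid absorption -2.09 and brush border -2.11 (day 1), interferon -2.06 and antimicrobial -0.36 (day 2) and interferon -0.62 (day 3), and lists no longer outside random lists were S phase -0.84 and goblet -0.66 (day 1), stem -0.76 and S phase -1.001 (day 2), stem -0.047 and Paneth 0.18 (day 3) and interferon -0.75 (day 5). Also, lists now above random lists were S phase 0.62 and antimicrobial 1.42 (day 3). In addition, lists now below random lists were interferon -3.17 (day 1), MHC class II -1.67 (day 2), goblet -1.39 (day 3) and G2 and M phase -0.53 and enterocyte -2.18 (day 5). In the remaining cells, lists on the opposite side of random lists were Paneth 1.12 (day 1), interferon -1.04, antimicrobial 0.88 and Paneth 1.08 (day 2) and antimicrobial 1.22 (day 3), and lists no longer outside random lists were stem -0.35 and enterocyte -0.17 (day 1), goblet -0.26 (day 2), interferon -0.21, MHC class II 0.34 and Paneth 0.11 (day 3) and interferon -0.53, enterocyte -0.13 and goblet 0.55 (day 5). Besides, lists now below random lists were MHC class II -1.21 and enterocyte -0.62 (day 2), G2 and M phase -0.33 (day 3) and G2 and M phase -0.83 and MHC class II -2.56 (day 5).

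With only the cells of the female pattern at 15 h as reference, over all kept cells, the list no longer outside random lists was MHC class II -0.38 (day 5), and lists now above random lists were MHC class II 0.54 (day 2), antimicrobial 0.78 (day 3) and antimicrobial 0.61 (2 days against 15 h). Among the remaining cells, the list on the opposite side of random lists was sex-linked check 3.37 (2 days against 15 h), and lists no longer outside random lists were interferon -0.34 and goblet 0.14 (day 1), antimicrobial 0.10 (day 3) and regenerative 0.42 (2 days against 15 h). Further, lists now above random lists were MHC class II 1.27 (day 2) and S phase 0.35 (2 days against 15 h). With only the cells of the male pattern at 15 h as reference, over all kept cells, the list no longer outside random lists was enterocyte -1.11 (day 2), and lists now above random lists were goblet 0.52 (day 3), Paneth 0.42 (day 5) and regenerative 0.66 and Paneth 0.34 (2 days against 15 h). Moreover, lists now below random lists were interferon -1.36 (day 1), S phase -0.18 and antimicrobial -0.84 (day 3), S phase -0.66 and G2 and M phase -0.61 (day 5) and G2 and M phase -0.23 (2 days against 15 h). Within the remaining cells, the list no longer outside random lists was Paneth -0.23 (day 1), and lists now below random lists were S phase -0.10 (day 3) and G2 and M phase -0.40 and MHC class II -1.43 (day 5).

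With every cell weighted equally, over all kept cells, the list on the opposite side of random lists was sex-linked check -1.04 (2 days against 15 h), and lists no longer outside random lists were enterocyte -0.52 (day 2), Paneth 0.28 (day 3) and G2 and M phase -0.12 and MHC class II 0.22 (Msi1 against Lgr5). Also, the list now above random lists was G2 and M phase 0.34 (day 3). In addition, lists now below random lists were interferon -0.77 (day 1), S phase -0.51 (day 5) and Paneth -0.94 (2 days against 15 h). For the remaining cells, lists no longer outside random lists were goblet -0.48 (day 5) and regenerative 0.52 (2 days against 15 h), and lists now below random lists were MHC class II -1.15 (day 5) and p53 -0.17 (Msi1 against Lgr5). With free RNA subtracted, over all kept cells, lists no longer outside random lists were MHC class II -1.04 (day 5) and MHC class II 0.14 (Msi1 against Lgr5), and lists now below random lists were interferon -1.38 (day 1) and G2 and M phase -0.48 (day 5). Inside the remaining cells, the list no longer outside random lists was regenerative 0.23 (2 days against 15 h), and lists now below random lists were p53 -0.21 and antimicrobial -0.39 (Msi1 against Lgr5). With median-of-ratios scaling, over all kept cells, lists now below random lists were G2 and M phase -0.17 and enterocyte -0.59 (day 5). In the remaining cells, the list on the opposite side of random lists was sex-linked check 1.11 (2 days against 15 h), and the list no longer outside random lists was goblet 0.28 (day 1). Besides, the list now above random lists was antimicrobial 0.30 (Msi1 against Lgr5). Further, lists now below random lists were MHC class II -0.71 (day 5) and p53 -0.24 (Msi1 against Lgr5). With no minimum level for list members, over all kept cells, lists now above random lists were antimicrobial 0.57 (day 3) and regenerative 0.53 (2 days against 15 h), and the list now below random lists was enterocyte -0.85 (day 5). Among the remaining cells, lists on the opposite side of random lists were lipid absorption -0.32 (day 2) and sex-linked check 0.94 (2 days against 15 h), and lists no longer outside random lists were interferon -0.25 and goblet 0.21 (day 1). Moreover, the list now above random lists was p53 0.25 (2 days against 15 h). With the stricter cell filter, over all kept cells, the list no longer outside random lists was MHC class II -1.04 (day 5), and the list now below random lists was G2 and M phase -0.48 (day 5). With a library total without mitochondrial genes and genes over 1%, over all kept cells, the list on the opposite side of random lists was sex-linked check -1.01 (2 days against 15 h), and the list now below random lists was G2 and M phase -0.37 (day 5). For the remaining cells, the list no longer outside random lists was goblet 0.21 (day 1). With all filtered barcodes, within the remaining cells, the list no longer outside random lists was Paneth -0.39 (day 2).

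Single-gene ratios that turned with the Msi1 library of 2 days as reference were, over all kept cells, Msi1 1.83, Ascl2 1.02, Ly6a 0.165 and Reg3g 1.27 at day 1, Msi1 1.82, Reg3b 1.85 and Reg3g 3.78 at day 2 and Msi1 1.26 at day 3. Within the remaining cells they were Ly6a 0.907, Reg3g 1.24, Lcn2 13.9 and Mptx2 1.64 at day 1 and Msi1 1.64 and Reg3b 13.5 at day 2.

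At clustering resolution 0.5, the enterocyte-like shares were 5.68% (day 0), 26.5% (Msi1 at 2 days) and 34.9% (Lgr5) and the Paneth-like share was 2.89% (day 5). The remaining-cell shares were 46.1% (Msi1 at 2 days) and 41% (Lgr5). At resolution 2, the remaining-cell shares were 70.6% (day 0), 44.9% (day 1), 48.3% (day 5) and 46.9% (Msi1 at 2 days) and the enterocyte-like shares were 11.4% (day 0), 0.246% (day 3), 13.2% (day 5) and 25.7% (Msi1 at 2 days). The goblet-like share was 12.6% (day 1) and the Paneth-like share was 2.89% (day 5). Without cell cycle genes, the remaining-cell shares were 72.5% (day 0) and 60.4% (Lgr5) and the enterocyte-like shares were 9.45% (day 0) and 15.5% (Lgr5). With each library clustered alone, the remaining-cell shares were 66.7% (day 0), 44% (day 1), 44% (day 2), 67.9% (day 3), 48.1% (day 5) and 58.8% (Msi1 at 2 days) and the goblet-like shares were 8.76% (day 0), 11.8% (day 1) and 20.4% (day 5). The enterocyte-like shares were 9.2% (day 1), 6.13% (day 2), 6.02% (day 3), 12.8% (day 5) and 13.9% (Msi1 at 2 days) and the Paneth-like shares were 29.6% (day 1) and 12.6% (day 5). The enteroendocrine-like share was 5.44% (day 1) and the tuft-like shares were 0% (day 1) and 2.08% (day 5). With the highest UMI minimum applied to every library, the enteroendocrine-like shares were 1.84% (day 3), 1.08% (day 5) and 1.98% (Lgr5) and the tuft-like shares were 0.0322% (day 3), 0.166% (day 5) and 1.6% (Msi1 at 2 days). The enterocyte-like shares were 34% (Msi1 at 2 days) and 15.7% (Lgr5) and the goblet-like share was 12.9% (Msi1 at 2 days). The Paneth-like share was 6.31% (Msi1 at 2 days). With high doublet scores left out, the remaining-cell share was 64.8% (Lgr5) and the goblet-like share was 15.7% (Lgr5).

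The shares of remaining cells with S phase UMIs, in the order of libraries given above, were when thinned to 2000 UMIs 76.9%, 66.2%, 48.9%, 76.3%, 63.9%, 78.9% and 71.4%. They were when thinned to 5000 UMIs 97.8%, 88.9%, 74.1%, 90%, 81.9%, 98.3% and 95.9%. The S phase shares were with at least 2 UMIs 95.5%, 87.6%, 74.5%, 88.4%, 80.7%, 95.7% and 93.9%. They became with at least 5 UMIs 73%, 60.2%, 49.2%, 72.3%, 58.5%, 75% and 65.2%, or with at least 10 UMIs 27.6%, 20.2%, 22.2%, 37.3%, 28.4%, 36.3% and 26.6%. The shares of remaining cells with G2 and M phase UMIs, in the order of libraries given above, were when thinned to 2000 UMIs 83%, 79.8%, 68.6%, 90.1%, 80.8%, 89.9% and 82.6%. They were when thinned to 5000 UMIs 98.3%, 96.5%, 93.9%, 99%, 94%, 99% and 98.1%. The G2 and M phase shares were with at least 2 UMIs 96.9%, 94.3%, 90.9%, 97.6%, 94.7%, 98% and 96.5%. They became with at least 5 UMIs 80.3%, 75.4%, 62.5%, 88%, 77.3%, 88.1% and 79.1%, or with at least 10 UMIs 53.2%, 52.7%, 41.1%, 75.3%, 57.3%, 71.2% and 59.8%.

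Without thinning, the shares of kept cells with Msi1 were 16.5%, 7.28%, 7.53%, 4.27%, 0.981%, 2.18% and 17.8%. At 5000 UMIs, the shares of kept cells with Msi1 were 3.89%, 1.46%, 1.77%, 0.768%, 0.798% and 7.53%, and day 5, at 0.174%, stayed inside its interval. Without thinning, the shares of kept cells with Lgr5 were 50.9%, 25.6%, 21.5%, 19.1%, 9.0%, 16.5% and 21.7%. At 5000 UMIs, the shares of kept cells with Lgr5 were 20.5%, 6.21%, 3.91%, 4.3%, 3.31%, 7.76% and 10.9%. Paneth genes in barcodes of 1 to 10 UMIs held 123733 CPM (day 0), 345937 CPM (day 2), 111327 CPM (day 3), 73010 CPM (day 5), 71266 CPM (Msi1 at 2 days) and 20078 CPM (Lgr5), each outside the counting interval of the main value. With classes taken from resolution 2, the regenerative list in the Msi1 against the Lgr5 library came to lie above random lists within enterocyte-like cells, at 0.51, and that of 2 days against 15 h inside them within the remaining cells, at 0.57.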

Other observations

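The p53 targets stood highest at day 2 and the regenerative genes at days 2 and 3, though the members measured differ between days. At day 3 Ly6a and Clu held 936 and 188 CPM. The stem list stood lowest at day 5. Antimicrobial genes stood below day 0 at days 1 and 2 and above it at day 5, but at day 2 they lay above random lists, at -0.36, against the Msi1 library of 2 days, and day 0 itself held male cells with 2.55-fold more Reg3b than its female cells. Within the day 3 library, cells with a Clu transcript held fewer G2 and M phase transcripts than the others.

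Of the tests in this part, the comparison of defensin RNA with empty droplets was chosen after free RNA values had been seen, the whole-transcript GC and shared-sequence tests were chosen only after the result of the first GC test had been seen, the patterns themselves were chosen from the data, and the limits of the immune cell test were written after a first form of it had been run. In the remaining cells of day 3, thinned to 3000 UMIs, at least 3 G2 and M phase UMIs were found in 88.2% (85.1 to 90.8) of 524 cells with a Clu UMI and in 96.8% of 1889 without, a difference of -8.6 percentage points with intervals apart. At that limit day 1 gave 90.9% and 87.3%, day 2 gave 82.7% and 81.9% and day 5 gave 83.3% and 89.9%, with intervals that overlap. Free RNA alone, at the uncertain share estimated from Paneth genes, would give a Clu UMI in 3.94% of the day 3 cells. The limit of at least 10 UMIs, chosen after the data were seen, gave 54.6% and 81.1% at day 3, 29.5% and 45.3% at day 2, 30% and 58.1% at day 5, and the opposite, 68.8% and 50.5%, at day 1. At day 3 cells with Ly6a, 73% against 85.3%, and with Cdkn1a, 58.7% against 88.7%, differed the same way, but cells with Cdkn1a went the other way at day 1, 56.2% against 45.8%.

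At day 5, 88 genes stood at least 4-fold below every other library, a limit set after a stricter one had left few genes, against 0 to 14 in the others, and 31 stood at least 4-fold above. A changed mix of the named classes is an unlikely cause, since within goblet-like cells their median log2 ratio to the Msi1 library of 2 days was -3.63. The choice of genes also favours a low value there. Goblet-like cells of these libraries lay in different clusters, so a changed mix inside this class is not excluded. At day 3 the median ratio of the 88 genes to day 0 was 0.04, but the genes were chosen for standing below every other library, so this value says nothing for or against a gradual course. Their transcript 3' ends were richer in GC by 3.8 percentage points (2.6 to 6.8) and their whole transcripts by 5.46 (3.76 to 7.16) than genes of the same level, which left both tests undecided, though over all genes the day 5 ratio showed no trend with GC, with medians of -0.16 in the lowest and -0.11 in the highest GC group. Sequence shared with other genes was found in 8 of 87 of them, 0.677 times the share of matched genes, and a step in the preparation of this library or a change in the tissue may be at work, and values of these genes at day 5, Ascl2 among them, should be read with that in mind.

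Interferon genes stood higher and Reg3b lower in the Msi1 library of 2 days than in that of 15 h. Within the 15 h library male and female cells differed by 0.06 in the median of 6 interferon genes, so no shift with sex was seen for those genes. Sex cannot be told apart from animal in this 1 library, so sex as a cause is not excluded. Other members were below 10 CPM there and did not enter this median. Among them, Isg15 was 2.31-fold (1.85 to 2.87) higher in the male cells, at 9.21 against 3.99 CPM. Immune cells among the sorted cells are an unlikely cause, since the interferon list lay at 2.37 within the remaining cells, which form no immune cluster. Male cells of the 15 h library held 2.55-fold more Reg3b than its female cells, while the male library of 2 days held less. For Reg3b the difference between these cells therefore points the other way. MHC class II genes lay 1.15 higher in the male cells. The state of single animals, such as their microbes, may lie behind such differences and could not be tested.

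The Paneth-like share stood higher at days 1 and 2 than at day 0. Loss of small cells to the higher UMI minimum of these libraries is unlikely to account for it, since with the same minimum of 12049 UMIs for all libraries the share at day 1 was 2.88 times that of day 0. Free Paneth RNA is unlikely to account for all of it, since Paneth-like cells with more RNA of defensins outside the marker list than empty droplets hold were still 29.3% (26.8 to 31.8) of cells at day 1 and 24.7% (22.4 to 27.1) at day 2, above the whole Paneth-like share of day 0, 10.6% (9.4 to 11.9). At day 2 only 334 of 534 Paneth-like cells passed this limit, so the size of that share is less sure. These defensins were not withheld from the clustering, and near-identical defensin genes can share reads. The 42.3 times higher Defa24 level of Paneth-like over remaining cells at day 1 adds nothing, because Defa24 helped to name the class. Loss of other cells after irradiation, more Paneth cells, or a sort that favoured them could each give such a share, and the counts do not separate these.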
